A study of Homo sapiens with 6 samples.

How the data were processed

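RNA of MCF7 cells was profiled by RNA sequencing 72 h after siRNA transfection in 6 libraries: 2 controls, 2 with TRPS1 knocked down and 2 with HDAC2 knocked down. The groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so the spread behind each p-value may be technical. The sample labels give the controls the treatment "None", while the treatment protocol lists a control siRNA.

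The submitters' processing notes name CASAVA 1.8, TopHat2, Cufflinks and Cuffdiff and the genome build hg38. The library kit, the counting program, its strand setting, the annotation and the normalization program are not given in the sources used here. The authors deposited 1 table per knockdown, each with the 2 control libraries and the 2 knockdown libraries, and each with 25369 genes. The deposited values are a signal of the form gene count divided by 1 factor per library, as the values themselves show. All values of a library are whole multiples of its smallest step, with 100% whole within a tolerance of 0.01 read. The reads so recovered were the same for the control libraries in both tables, and the factors lay within 2.64% of median-ratio size factors computed from those reads. The controls were thus scaled separately in each table, and each knockdown was compared with the controls within its own table. In the text, a deposited value is called a normalized count. A copy of each table with other separators held the same values and was not used.

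The recovered reads assigned to genes were 1982497 and 1154812 in the controls, 1058065 and 981507 in the TRPS1 knockdown, and 1266113 and 991040 in the HDAC2 knockdown. At this depth, 3 reads equal 1.61 to 3.91 normalized counts in the TRPS1 table and 1.74 to 3.95 in the HDAC2 table. Read intervals given below are exact binomial 95% intervals and cover counting error only.

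Genes with a normalized count of at least 10 in at least 2 libraries of a table were tested with limma 3.58.1 on log2(value + 1), with a mean-variance trend, in R 4.3.3. Each gene's variance came mostly from that trend over all genes and less from its own replicates. The trend had 16.9 degrees of freedom for TRPS1, 19.3 for HDAC2 and 33.8 between the knockdowns, against 2, 2 and 3 of the gene's own. A fold change is on that scale, which understates the change of low genes. P-values are 2-sided and were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The 2 knockdowns were compared with each other in 1 fit of all 6 libraries, on recovered reads scaled together by median-ratio factors. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run as alternatives. An adjusted p that DESeq2 left empty was kept empty.

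Before the data were examined, 33 gene lists were fixed with 792 different genes. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with adjustment over 60 tests, and again with an estimated correlation. Members were also adjusted over the list alone. Named genes follow a rule fixed at the same time. TRPS1, HDAC2 and TP63 are always named. For each comparison, the rule takes the 10 largest rises and 10 largest falls past the threshold. These genes have both libraries of one group beyond both of the other and a mean above the median of the genes tested. From each list described, up to 4 members with the smallest p are named. For the shared response, up to 5 genes called in both comparisons are named per direction. Genes named outside the rule are said to be.

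Gene positions and overlaps are from GENCODE release 29 on hg38, matched by gene identifier for 99.728% of the genes. Of the matched genes, 8137 have an exon that overlaps an exon of a gene on the opposite strand, and 17163 do not. Pairs were compared where the overlap was at least 200 bp. For the share of the lower row in a pair, the higher row had at least 100 normalized counts and at least 10 times the lower, which had at least 20.

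Alternatives included pseudocounts of 0.5 and 10, no filter, a minimum of 50, TMM scaling, quantile normalization, a replicate block, fits without the trend or with robust variances, a 1.2-fold minimum and each library left out. A fit on the genes with and without opposite-strand overlap apart was added after seeing the data. The tests were checked on simulated reads drawn from the means and depths of these libraries, with 2-fold and 4-fold changes in known genes. In the TRPS1 simulation of 8065 genes, limma called 34.4% of the 2-fold and 79.6% of the 4-fold changes, and 5.22% of its calls were false. In the HDAC2 simulation of 8419 genes, it called 26.4% and 73.7%, and 1.04% of its calls were false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.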

Results

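MCF7, a luminal, estrogen receptor-positive breast cancer cell line, was transfected for 72 h with siRNA against TRPS1 or HDAC2 and compared with control cells. TRPS1 is a GATA-type zinc finger transcription factor, and HDAC2 is a histone deacetylase. The series asks how TRPS1 represses transcription in breast cancer cells. Each of the 3 groups had 2 libraries. Between 981507 and 1982497 reads per library were assigned to genes, and control replicate 1 was the deepest. Replicates of each group differed beyond sampling noise, with a chi-square per degree of freedom of 4.53 in the controls, 2.72 in the TRPS1 knockdown and 2.69 in the HDAC2 knockdown.

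Most of the highest rows of the tables were genes whose exons overlap another gene on the opposite strand. The row with the highest mean was KRT8, itself a luminal keratin, at 58070 normalized counts, whose exons overlap KRT18 on the opposite strand, while the KRT18 row held 499. SH3D19, which overlaps the ribosomal protein gene RPS3A, held 57600 against 175 for RPS3A itself. ATG10 held 21850 against 83.8 for RPS23, and BEST1 held 10880 against 60.7 for the ferritin gene FTH1. ACTB, a cytoskeletal actin with no annotated opposite-strand exon, ranged from 60.9 to 124 over the 6 libraries. Among the 100 rows with the highest mean, 98 had exons overlapping a gene on the opposite strand, compared with 32.1% of all rows. Of 37 listed ribosomal protein genes without such overlap, 1 was among the 500 highest rows. Without a stated strand setting, the reads of a gene and its opposite-strand partner cannot be told apart by row name, so each named row is given with its partner where one is annotated. For rows without a partner, TRPS1 among them, the sources do not settle whether the reads are the gene's own or a share carried over from the other strand. In the latter case a fold change also holds any change of that share. Rows without overlap held 15.4% and 12.4% of the assigned reads in the controls, 11.7% and 10.9% in the TRPS1 knockdown, and 12.5% and 12.1% in the HDAC2 knockdown.

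Within opposite-strand pairs whose rows lay at least 10-fold apart, the median change of the log2 ratio of the lower to the higher row was -0.352 (95% bootstrap interval over pairs, -0.435 to -0.294) in the TRPS1 knockdown and -0.265 (-0.363 to -0.135) in the HDAC2 knockdown. Over 173 pairs the median share was 6.48% and 5.09% in the controls, 4.88% and 4.38% in the TRPS1 knockdown, and 5.18% and 4.61% in the HDAC2 knockdown. Control replicate 1 stood highest, and HDAC2 knockdown replicate 1 lay above control replicate 2. The intervals cover the spread over pairs and not that between libraries. Rows without opposite-strand overlap had a median log2 fold change of -0.23 in the TRPS1 knockdown, against 0.07 for rows with overlap. The same medians were -0.14 and 0.03 in the HDAC2 knockdown.

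**Figure D1:**
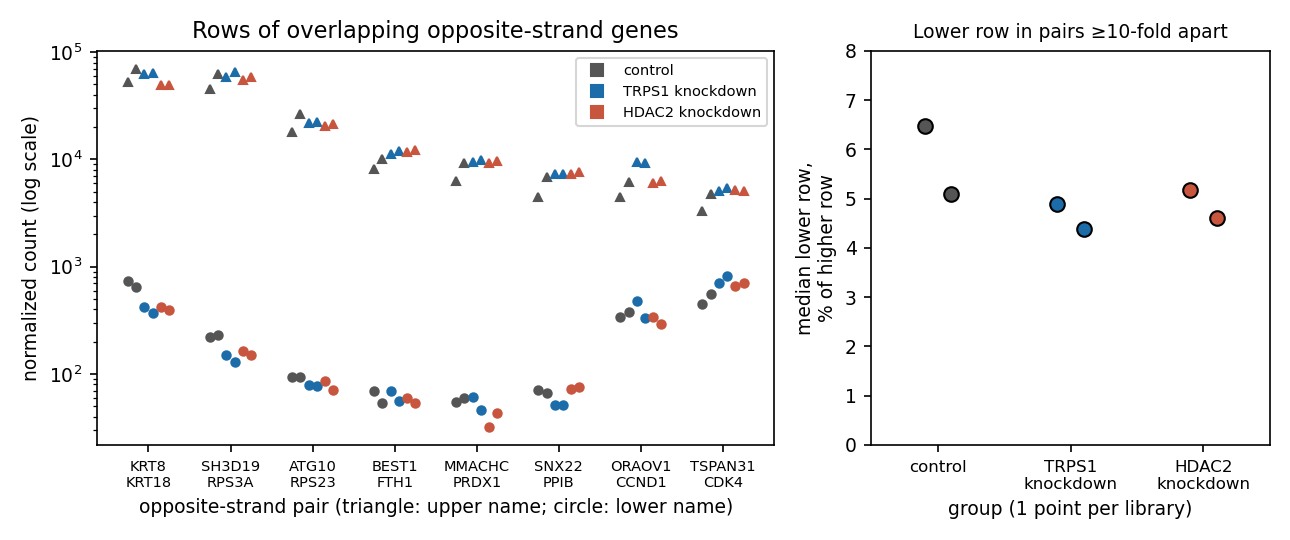
Left, normalized counts (log axis) of both rows of 8 opposite-strand gene pairs, 1 symbol per library, coloured by group, with means of 58070 and 499 for KRT8 and KRT18. Right, for each library, the median of the lower row as a percentage of the higher row over 173 pairs at least 10-fold apart, which runs from 4.38% to 6.48%.

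The knocked-down genes were lowest in their own knockdown. TRPS1 (ENSG00000104447, chromosome 8, 115408496 to 115809673, minus strand, with no annotated opposite-strand exon) fell from 73.2 ± 1.90 normalized counts in the controls to 16.0 ± 12.5 in the TRPS1 knockdown (SD, n = 2), a log2 fold change of -2.35 with an SE of 0.45 (limma, adjusted p = 0.0272). HDAC2 (ENSG00000196591, chromosome 6, 113933028 to 114011308, minus strand, overlapping HDAC2-AS2 by 69 bp) had 41.7 ± 11.4 normalized counts in the controls and 6.80 ± 5.27 in the HDAC2 knockdown (SD, n = 2). Its log2 fold change was -2.61 with an SE of 0.57, which missed the threshold (limma, adjusted p = 0.0501). In the TRPS1 knockdown HDAC2 had 18.9 ± 4.67 normalized counts against 38.6 ± 10.6 (log2 fold change -0.99, limma, adjusted p = 0.338). TRPS1 had 51.2 ± 7.26 against 79.1 ± 1.98 in the HDAC2 knockdown (log2 fold change -0.62, limma, adjusted p = 0.404). TP63 (ENSG00000073282, chromosome 3, 189631416 to 189897279), a basal epithelial transcription factor, had 0 reads in both controls, 2 and 0 in the TRPS1 knockdown, and 0 and 3 in the HDAC2 knockdown. These are too few reads to judge a change. The TP63 row has no annotated opposite-strand exon, so the limit given for rows without a partner applies to it too. The TRPS1 call was lost without a filter on low values (limma, adjusted p = 0.141), with TMM scaling (0.052) or quantile normalization (0.108), with a 1.2-fold minimum (0.0914), among genes without opposite-strand overlap (0.0752) and without the variance trend (0.416). It passed in edgeR (0.0153), with a pseudocount of 0.5 (0.0279) or 10 (0.01115), a minimum of 50 (0.0154), the replicate block (0.00406) and robust variances (0.0186). With 1 library left out, its log2 fold change ran from -3.18 to -1.52, and it was -2.377 and -2.325 without control replicate 1 and 2. Such fits leave 1 library in a group, so this range does not show that the call survives the loss of a library. HDAC2 passed in edgeR (adjusted p = 0.0176), and in limma with a pseudocount of 10 (0.0246), without a filter (0.0316), with the replicate block (0.00306), with robust variances (0.021) and among genes with opposite-strand overlap (0.0113). It did not pass with a pseudocount of 0.5 (0.0524), TMM scaling (0.0666), quantile normalization (0.0896), a 1.2-fold minimum (0.147) or without the variance trend (0.447). With 1 library left out, its log2 fold change ran from -3.36 to -1.86.

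**Figure D2:**
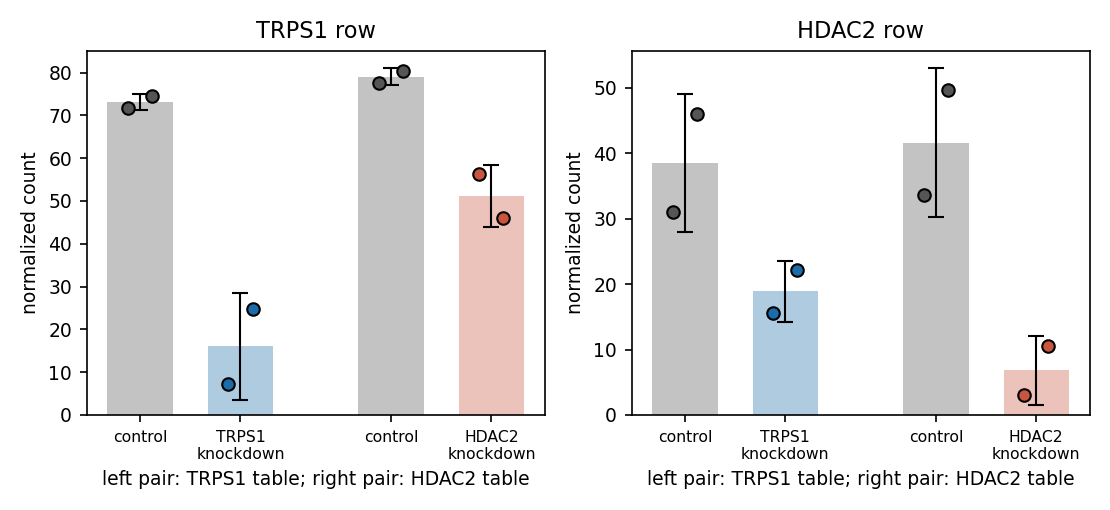
Normalized counts of the TRPS1 row (left) and the HDAC2 row (right) in both tables, with libraries as points, means as bars and SDs as error bars (n = 2). TRPS1 is at 16.0 in the TRPS1 knockdown against 73.2 in its controls, and HDAC2 at 6.80 in the HDAC2 knockdown against 41.7.

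In cells with TRPS1 knocked down, 29 rows changed against the controls, 12 higher and 17 lower. The largest rise was HECTD2, a HECT-domain ubiquitin ligase, from 58.9 ± 12.8 to 296 ± 21.1 normalized counts (SD, n = 2; log2 fold change 2.32, SE 0.25). Falls included FASN, the fatty acid synthase, from 298 ± 2.29 to 110 ± 14.6 (log2 fold change -1.44, SE 0.23), and CRABP2, a retinoic acid-binding protein, from 87.0 ± 4.03 to 28.7 ± 0.0369 (log2 fold change -1.56, SE 0.31). DSCAM-AS1, a long noncoding RNA of luminal breast cancer, fell by 1.67 on the log2 scale (SE 0.32). The question was which genes respond to the loss of TRPS1.

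Among the other rises in the TRPS1 knockdown, MICA, a stress-induced ligand of the natural killer cell receptor NKG2D, changed by 2.25 on the log2 scale (SE 0.45). IL17RC, a subunit of the interleukin-17 receptor, changed by 1.41, and PRSS12, a secreted serine protease, by 1.28. None of these has an annotated opposite-strand exon, so the limit given for rows without a partner applies to them. Rises in rows with a partner were JRK (partner PSCA) by 1.85, TM4SF18 (AC093001.1) by 1.81, ACSS3 (PPFIA2 and LIN7A) by 1.60, RRP7BP (SERHL2) by 1.41, KIAA1614 (KIAA1614-AS1 and AL162431.2) by 1.21 and AKTIP (RBL2) by 1.14. RBL2 encodes a retinoblastoma-family protein, and RRP7BP is a pseudogene with a near copy, RRP7A, so its reads are uncertain. Adjusted p-values of the named rises ran up to 0.0474 (limma).

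The largest fall was HIST2H3A, a replication-dependent histone H3 gene with near-identical copies and HIST2H4B on the opposite strand, so its reads are uncertain. It had 21 and 4 reads in the TRPS1 knockdown against 188 and 206 in the controls, a scaled ratio of 11.4% (95% interval 7.30% to 17.1%). SELENOI, an ethanolamine phosphotransferase (partner ADGRF3), fell by 2.17 on the log2 scale, and FLNB, an actin crosslinker (partner FLNB-AS1), fell by 1.78. UHMK1, a serine/threonine kinase, had a log2 fold change of -1.92. GAPDH (partner AC006064.4) fell from 963 ± 123 to 353 ± 29.1 normalized counts (log2 fold change -1.44, SE 0.21). DDR1, a collagen receptor kinase, fell by 1.36.

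The limma test called 29 of 8122 genes, with 982 at an unadjusted p under 0.05, where edgeR called 58 (29 higher, 29 lower) and DESeq2 125 (95 higher, 30 lower). The split turned with the library left out. Without control replicate 1 there were 25 calls (17 higher, 8 lower) and 10 of the 20 named genes passed, without control replicate 2 there were 285 (254 and 31) and 16, without TRPS1 knockdown replicate 1 there were 278 (33 and 245) and 20, and without its replicate 2 there were 52 (9 and 43) and 12. There were 7 calls without a filter or with a 1.2-fold minimum (4 higher, 3 lower in each), 47 with a pseudocount of 10, 102 with a minimum of 50 (57 and 45) and 0 without the variance trend. Among the genes without opposite-strand overlap, rescaled on their own, there were 3 (3 higher, 0 lower), against 4 higher and 11 lower of these genes in the main fit. No fall in this class passed there, FASN, CRABP2 and DSCAM-AS1 included.

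**Figure D3:**
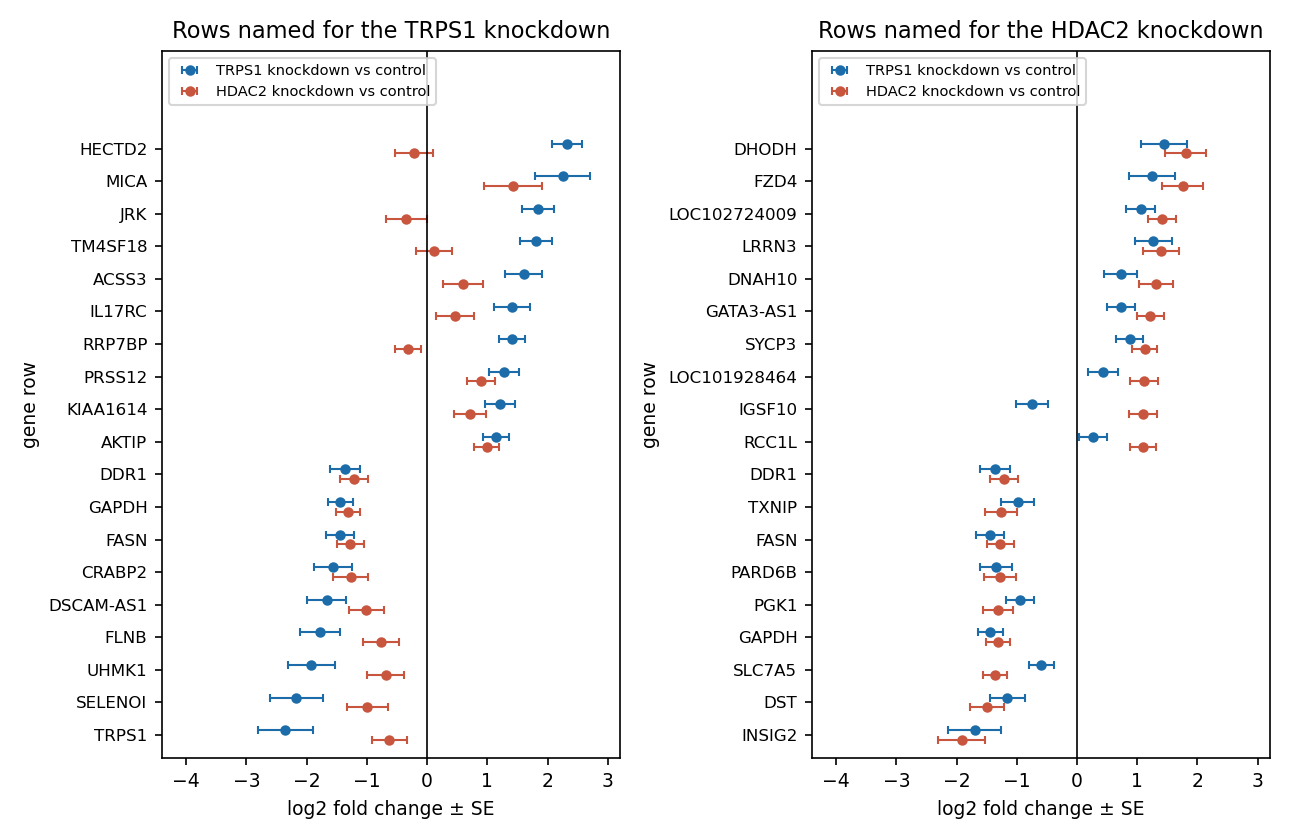
Log2 fold change against the controls (x axis, error bars are SEs, n = 2 libraries per group) of the rows named for the TRPS1 knockdown (left) and the HDAC2 knockdown (right), each shown in both knockdowns, without HIST2H3A, which had 3 reads in the HDAC2 knockdown. HECTD2 stands at 2.32 in the TRPS1 knockdown, and FASN at -1.44 and -1.28.

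Of 30 gene lists tested, 7 moved in the TRPS1 knockdown, all lower. None held with an estimated correlation (adjusted p = 0.585 for each). The cytosolic ribosomal protein list had 53 tested members and a median log2 fold change of -0.53 (camera, adjusted p = 5.19e-12). Over all genes 0 members passed, and 11 fell when adjusted over the list alone, led by RPL35 (-1.23, partner WDR38), RPS14 (-1.23), RPLP0 (-0.85) and RPS11 (-1.04). The glycolysis and hypoxia list, with 30 members, had a median of -0.52 (camera, adjusted p = 2.99e-08). GAPDH passed over all genes, and 12 fell and 1 rose when adjusted over the list alone, among them TPI1 (-0.93, partner SPSB2), PGK1 (-0.95) and ALDOA (-0.76, partner AC093512.1), enzymes of glycolysis. The share of the lower row within opposite-strand pairs was 4.88% and 4.38% here against 6.48% and 5.09% in the controls. Whether either list follows it library by library was not tested.

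Replication-dependent histones had 13 tested members, all with a lower value, and a median of -0.46 (camera, adjusted p = 0.00188). Over all genes 0 passed, and HIST1H2BC (-1.47) fell when adjusted over the list alone. The list of G2/M and mitosis genes, with 45 members, had a median of -0.49 (camera, adjusted p = 0.00642). Of these 0 passed over all genes, and ECT2 (-1.36), an activator of cytokinesis, and UBE2S (-1.42), a ubiquitin-conjugating enzyme of mitotic exit, fell when adjusted over the list alone. ANLN (partner KIAA0895) was at -1.15, without passing. The GATA family and TRPS1 cofactor list had 10 members and a median of -0.59 (camera, adjusted p = 0.0268). It contains TRPS1 itself, the member that passed over all genes, and CHD4 (-0.85), the helicase of the NuRD repressor complex (partner AC006064.2), fell when adjusted over the list alone (limma, adjusted p = 0.0424). Adjusted over the list of NuRD subunits, CHD4 did not pass (0.11), nor over all genes (0.23).

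Estrogen-induced genes had 24 members and a median of -0.31 (camera, adjusted p = 0.0326). Over all genes 0 passed, and XBP1 (-1.14) and TFF1 (-1.73), both classic estrogen receptor targets, fell when adjusted over the list alone, while GREB1 (-0.88) and AREG (-1.15) did not pass. The fatty acid synthesis list had 12 members and a median of -0.25 (camera, adjusted p = 0.043). FASN and SCD, the stearoyl-CoA desaturase (log2 fold change -1.35, SE 0.24), passed over all genes and over the list alone, and ELOVL5 (-0.78) and ME1 (1.61) did not. Whether these lists follow the lower-row shares given above was not tested either, and camera's adjusted p = 0.585 with an estimated correlation holds for each. With 1 library left out at a time, the ribosomal, glycolysis and histone lists stayed past the threshold, while the others lost it. Without control replicate 1 the G2/M list (adjusted p = 0.143) and the estrogen list (0.142) did not pass, and without control replicate 2 the cofactor list (0.36) did not. Without TRPS1 knockdown replicate 1 the fatty acid (0.147) and cofactor (0.175) lists did not pass, and without its replicate 2 the G2/M (0.155), estrogen (0.208) and fatty acid (0.105) lists did not. Among genes without opposite-strand overlap, the ribosomal (adjusted p = 2.65e-05), glycolysis (0.0127) and histone (0.0396) lists passed. The other 23 lists did not pass, with medians from -0.79 to 0.59 (adjusted p from 0.0917). Luminal epithelial markers were among them at a median of -0.14 (camera, adjusted p = 0.0959), although KRT19 fell by 1.11 (limma, adjusted p = 0.0273).

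**Figure D4:**
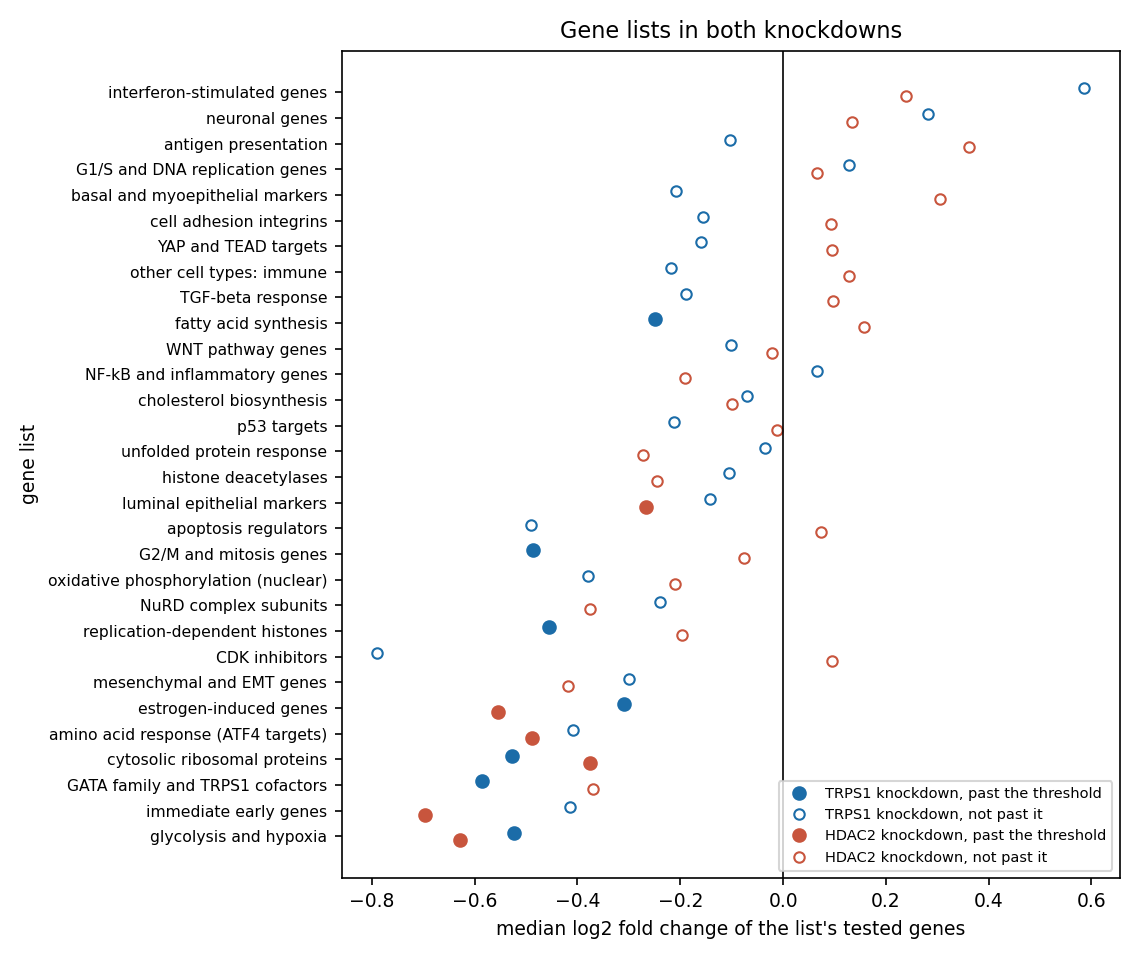
Median log2 fold change (x axis) of the tested members of each of 30 gene lists in the TRPS1 knockdown (blue) and the HDAC2 knockdown (red). Filled points, 7 and 6 in number and all below 0, passed camera's test with a preset correlation, and open points did not.

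In cells with HDAC2 knocked down, 27 rows changed against the controls, 12 higher and 15 lower. DHODH, an enzyme of pyrimidine synthesis, rose from 27.4 ± 12 to 93.8 ± 0.569 normalized counts (SD, n = 2; limma, adjusted p = 0.0205), and LRRN3, a neuronal leucine-rich repeat protein, by 1.39 on the log2 scale (SE 0.30). SLC7A5, a large amino acid transporter (partner AC126696.2), fell from 1024 ± 91.9 to 398 ± 29.4 (log2 fold change -1.36, SE 0.20). INSIG2, an anchor of sterol sensing in the endoplasmic reticulum, fell from 70.0 ± 8.06 to 19.2 ± 10.4 (log2 fold change -1.91, SE 0.39). The comparison sets the loss of a deacetylase beside that of TRPS1.

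Other rises in the HDAC2 knockdown were FZD4 (partner PRSS23) by 1.75, DNAH10 (DNAH10OS and CCDC92) by 1.31 and RCC1L, with no annotated partner, by 1.09. GATA3-AS1 (AL390294.1), a noncoding RNA next to the luminal regulator GATA3, rose by 1.21. SYCP3 (CHPT1) rose by 1.13, LOC101928464 (ZNF433 and AC008770.1) by 1.11 and IGSF10 (MED12L) by 1.10. LOC102724009 (KIF1C) rose from 217 to 561 normalized counts. The partner CHPT1 encodes a choline phosphotransferase. Adjusted p-values of the named rises ran up to 0.0491 (limma).

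HIST2H3A had 1 and 2 reads in the HDAC2 knockdown against 188 and 206 in the controls, a scaled ratio of 1.17% (95% interval 0.24% to 3.44%), and its reads are uncertain as stated. DST, a linker of the cytoskeleton, fell from 128 ± 9.73 to 45.1 ± 8.76 normalized counts. PARD6B, a cell polarity protein, fell by 1.28 on the log2 scale, and TXNIP, a thioredoxin-binding protein, had a log2 fold change of -1.26. GAPDH fell by 1.31, FASN by 1.28 and DDR1 by 1.21. PGK1, a glycolytic kinase, fell from 211 ± 3.07 to 85.7 ± 20.7 normalized counts (log2 fold change -1.31, SE 0.25; limma, adjusted p = 0.0212).

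The limma test called 27 of 8480 genes, with 1008 at an unadjusted p under 0.05, where edgeR called 71 and DESeq2 105 (71 higher, 34 lower). Here too the split turned with the library left out. Without control replicate 1 there were 150 calls (77 higher, 73 lower), without control replicate 2 there were 302 (256 and 46), without HDAC2 knockdown replicate 1 there were 110 (12 and 98) with 14 of the 20 named genes, and without its replicate 2 there were 36 (7 and 29) with 8 of them. There were 52 calls with a pseudocount of 10, 138 with a minimum of 50 (71 and 67), 58 with quantile normalization, 50 with robust variances, 2 with a 1.2-fold minimum and 0 without the variance trend. When each class was rescaled on its own, there were 3 (2 and 1) among genes without opposite-strand overlap and 69 (41 and 28) among those with it. Of the 10 named genes without overlap, 2 passed there and 8 did not. DHODH, LRRN3, INSIG2, DST and PGK1 are among these 10, and the limit given for rows without a partner applies to them.

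In the HDAC2 knockdown 6 lists moved, all lower, and for each the adjusted p = 0.585 with an estimated correlation. Cytosolic ribosomal proteins had 53 members and a median log2 fold change of -0.38 (camera, adjusted p = 1.97e-09). Over all genes 0 passed, and 9 fell when adjusted over the list alone, led by RPL18 (-1.19, partner SPHK2), RPS14 (-0.92), RPL35 (-1.06, partner WDR38) and RPS19 (-0.95). Glycolysis and hypoxia genes had 30 members and a median of -0.63 (camera, adjusted p = 2.13e-08). GAPDH and PGK1 passed over all genes, and 11 fell and 1 rose when adjusted over the list alone, among them ENO1 (-0.80, partner ENO1-AS1) and TPI1 (-0.81). The amino acid response list of ATF4 targets had 17 members and a median of -0.49 (camera, adjusted p = 0.00301). SLC7A5 passed over all genes, and its partner subunit SLC3A2 (-1.25) fell as well when adjusted over the list alone, while MTHFD2 (-0.83, partners SLC4A5 and AC006030.1) and SLC1A5 (-0.74, partners AC008622.2 and FKRP) did not pass. The lower-row share was 5.18% and 4.61% in the HDAC2 knockdown against 6.48% and 5.09% in the controls. Whether these lists follow it library by library was not tested.

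Estrogen-induced genes had 25 members and a median of -0.55 (camera, adjusted p = 0.00717). XBP1 (-1.11) passed over all genes (limma, adjusted p = 0.0487), CA12 (-1.24) and TFF1 (-1.19) fell when adjusted over the list alone, and IRS1 (0.53) did not pass. Immediate early genes had 9 members and a median of -0.70 (camera, adjusted p = 0.0283), of which IER3 (-1.07, partner IER3-AS1) fell when adjusted over the list alone, and JUNB (-0.70, partner HOOK2), IER2 (-0.99, partner AC011446.2) and EGR2 (-1.78) did not pass. Luminal epithelial markers had 17 members and a median of -0.27 (camera, adjusted p = 0.043). XBP1 passed over all genes, the keratins KRT19 (-0.92) and KRT18 (-0.82, partner KRT8) fell when adjusted over the list alone, and ELF3 (0.61, partner ELF3-AS1) did not pass. Whether these 3 lists follow the lower-row shares was not tested either, and camera's adjusted p = 0.585 with an estimated correlation applies to each. With 1 library left out at a time, the ribosomal, glycolysis and ATF4 lists stayed past the threshold, while the others lost it. Without control replicate 1 the estrogen (adjusted p = 0.142) and immediate early (0.0643) lists did not pass, and without control replicate 2 the immediate early list (0.3) did not. Without HDAC2 knockdown replicate 1 the luminal list (0.183) did not pass, and without its replicate 2 the luminal (0.231) and immediate early (0.119) lists did not. Among genes without opposite-strand overlap, the ribosomal (adjusted p = 0.000312), glycolysis (0.00169) and estrogen (0.0219) lists passed. The other 24 lists did not pass, with medians from -0.42 to 0.36 (adjusted p from 0.0897). For fatty acid synthesis genes the median was 0.16 while the mean was -0.04, and camera's direction was lower (adjusted p = 0.395).

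Markers of other cell types gave no called list. The immune list had 3 tested members with medians of -0.22 in the TRPS1 knockdown (camera, adjusted p = 0.97) and 0.13 in the HDAC2 knockdown (0.97). Fibroblast and endothelial markers had too few members above the minimum to be tested, and 0 of 15 mitochondrially encoded genes were in the tables.

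Several of the same rows were lower in both knockdowns. Of 7822 genes tested in both, 8 were called in both in the same direction, 1 higher and 7 lower, and 0 in opposite directions. AKTIP (partner RBL2) rose by 1.14 and 0.99 on the log2 scale in the TRPS1 and HDAC2 knockdowns. Among the falls, GAPDH was at -1.44 and -1.31, PARD6B at -1.34 and -1.28, FASN at -1.44 and -1.28 and DDR1 at -1.36 and -1.21, and HIST2H3A had the read ratios given above. Of the rest, SCD was at -1.35 and -1.02, and RN7SL2, a signal recognition particle RNA with near-identical copies, at -1.33 and -1.17. RN7SL2 was named outside the rule, after its values were seen. Of the 7 falls, 5 (PARD6B, FASN, DDR1, RN7SL2 and SCD) were in rows without opposite-strand overlap, the class with medians of -0.23 and -0.14. That class held 3373 of the 7822 genes tested in both.

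Both comparisons used the same controls, whose label "None" leaves open whether they were transfected. Independent lists of these sizes would share 0.0184 higher and 0.0326 lower genes, and 100 simulations of unchanged groups against shared controls gave 0 shared calls, which does not show how far shared controls make lists of real calls coincide. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.541, against a simulated mean of 0.504 (0.472 to 0.53). Their covariance was 0.192 against a simulated 0.119, a difference of 0.0738. The simulation gave all groups the same dispersion at a given read level. The control replicates differed most, with a chi-square per degree of freedom of 4.53 against 2.72 and 2.69 in the knockdowns, a measure that also rises with depth. The simulated values may thus be too low. The controls cannot be split into parts of 2 libraries, so part of the excess may come from the shared controls. With a different control library for each knockdown the correlation was 0.17 or 0.249. The 8 shared calls became 52 in DESeq2 (34 higher, 18 lower), 12 without control replicate 1 (7 and 5), 164 without control replicate 2 (144 and 20), 4 without TRPS1 knockdown replicate 2 (2 and 2), 5 without HDAC2 knockdown replicate 1 and 1 without its replicate 2, and 0 among genes without opposite-strand overlap.

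Set against each other, the knockdowns differed in 36 rows, 27 higher and 9 lower in the TRPS1 knockdown. HECTD2 had 296 ± 15.9 normalized counts in the TRPS1 knockdown and 50.6 ± 10.3 in the HDAC2 knockdown (SD, n = 2; log2 difference 2.54, SE 0.27). SRMS, a non-receptor tyrosine kinase (partner AL121829.2), had 238 ± 7.15 against 61.9 ± 23.1 (log2 difference 1.98). BBIP1, whose partner PDCD4 (beside AL158163.2) encodes an inhibitor of translation, had 1151 ± 190 against 2984 ± 104 (log2 difference -1.38). TRPS1 itself differed by -1.73 (limma, adjusted p = 0.042), and HDAC2 was at 1.61 without passing (0.243).

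Other rows higher in the TRPS1 knockdown were LOC388882 (log2 difference 2.26), JRK (2.19, partner PSCA), RRP7BP (1.72, partner SERHL2), TM4SF18 (1.69, partner AC093001.1), MIPEP (1.62, partner PCOTH), ATP5S (1.44, partners CDKL1, AL359397.2 and L2HGDH), RER1 (1.32, partner PEX10, a peroxisome assembly gene) and RRP7A (1.28, partner SERHL). Lower rows were IGSF10 (-1.84, partner MED12L), MYO1E (-1.29, partners AC092757.2 and FAM81A), CALM1, a calmodulin gene (-1.10, partner AL512791.1), and MAPK6, an atypical MAP kinase (-1.08). Of the 36 rows, 24 higher and 5 lower ones had opposite-strand overlap, as did 4752 of the 8699 rows tested.

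The limma test covered 8699 genes, with 904 at an unadjusted p under 0.05, where edgeR called 50 and DESeq2 54, and the split was 27 higher and 4 lower with TMM scaling and 39 and 26 with quantile normalization. Calls numbered 136 without control replicate 1, 134 without control replicate 2, 25 without TRPS1 knockdown replicate 1 (7 higher, 18 lower), 17 without its replicate 2 (7 and 10), 8 without HDAC2 knockdown replicate 1, 12 without its replicate 2, 66 with a pseudocount of 10, 106 with a minimum of 50, 12 without a filter or with a 1.2-fold minimum, 2 among genes without opposite-strand overlap and 0 without the variance trend.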

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

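The rows below are those named by the rule for the comparison of the 2 knockdowns. Each differed between the TRPS1 and HDAC2 knockdowns in the planned test of the difference itself (limma, adjusted p up to 0.0481), and each value is the log2 difference, TRPS1 knockdown minus HDAC2 knockdown.

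Rows higher in the TRPS1 knockdown were HECTD2 (2.54), LOC388882 (2.26), JRK (2.19), SRMS (1.98), RRP7BP (1.72), TM4SF18 (1.69), MIPEP (1.62), ATP5S (1.44), RER1 (1.32) and RRP7A (1.28). Rows lower there were IGSF10 (-1.84), TRPS1 (-1.73), BBIP1 (-1.38), MYO1E (-1.29), CALM1 (-1.10) and MAPK6 (-1.08). HECTD2, LOC388882, TRPS1 and MAPK6 have no annotated exon on the opposite strand. Against the controls, the log2 fold change of IGSF10 was -0.75 in the TRPS1 knockdown (limma, adjusted p = 0.253) and 1.10 in the HDAC2 knockdown (0.039). In the same order, RER1 was at 0.40 (0.456) and -0.92 (0.0654), and RRP7BP at 1.41 (0.00373) and -0.32 (0.578). Without TRPS1 knockdown replicate 1, 7 of these 16 rows passed, without its replicate 2, 9 did, without HDAC2 knockdown replicate 1, 7 did, and without its replicate 2, 8 did.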

How the results depend on the processing

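The fits by opposite-strand overlap were chosen after seeing the data. All other settings were fixed before. Over 58 named-gene results and their alternatives, 742 of 998 values stayed on their side of the threshold, 256 no longer passed it and 0 changed direction; of 181 list values, 136 stayed and 45 no longer passed. The cause was not tested except where fewer genes or libraries entered. Apart from the genes always named, the named genes had been chosen past the threshold, with both libraries of a group beyond both of the other. For such genes, leaving out a library or changing the pseudocount, filter, trend or variance setting cannot reverse the direction. The 0 changes of direction are therefore no measure of stability under those settings. Depth limits what low genes can show, as the lowest library held 981507 reads. With a minimum of 50, HDAC2 itself gives no value. No deposited p-values were used here, so calls from the authors' own test were not run. DESeq2 gave no adjusted p for TRPS1 or HDAC2 in their own knockdowns.

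The main counts were 29 genes in the TRPS1 knockdown, 27 in the HDAC2 knockdown and 36 between them. In that order, they were 47, 52 and 66 with a pseudocount of 10, 102, 138 and 106 with a minimum of 50, 7, 2 and 12 with a 1.2-fold minimum, 0, 0 and 0 without the variance trend, and 3, 3 and 2 for genes without opposite-strand overlap. Without a filter there were 7 genes in the TRPS1 knockdown and 12 between the knockdowns. Quantile normalization gave 58 in the HDAC2 knockdown and 65 between the knockdowns, and robust variances gave 50 in the HDAC2 knockdown. For genes with overlap there were 11 in the TRPS1 knockdown and 69 in the HDAC2 knockdown. Calls from edgeR were 58 and 71, and from DESeq2 125 and 105, for TRPS1 and HDAC2. With 1 library left out at a time, the range was 25 to 285 for TRPS1, 36 to 302 for HDAC2 and 8 to 136 between them; a lone library was assumed to vary like the other groups.

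The replicate block gave 43 genes for TRPS1, 98 for HDAC2 and 23 between the knockdowns, and 17 shared calls. Same-numbered libraries did not deviate together (correlations -0.022 and -0.043), and with 2 pairs the numbers do not pair the samples. HDAC2 passed with the replicate block at a log2 fold change of -2.61 (adjusted p = 0.00306).

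The log2 fold change of TRPS1 in its knockdown no longer passed at -2.35 without a filter, without the trend and with a 1.2-fold minimum, at -2.34 with TMM scaling, at -2.23 with quantile normalization and at -2.16 among genes without overlap. That of HDAC2 passed at -1.64 with a pseudocount of 10, at -2.61 without a filter and with robust variances, at -2.63 among genes with overlap and at -2.64 in edgeR. With 1 library left out, TRPS1 ranged from -3.18 to -1.52 and HDAC2 from -3.36 to -1.86. Such fits leave 1 library in a group, so these ranges do not show whether either gene stays past the threshold.

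Lists past the threshold numbered 7 for TRPS1 and 6 for HDAC2. With an estimated correlation there were 0 and 0, and among genes without overlap 3 and 3; among genes with overlap there were 3 for TRPS1. With 1 library left out, they ranged from 4 to 6 and from 4 to 5.

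The correlation of the 2 knockdowns' fold changes was 0.541, and 0.637 in DESeq2, 0.17 and 0.249 with separate controls and from 0.449 to 0.67 with 1 library left out. The 8 shared calls became 14 with a pseudocount of 10 or robust variances, 3 without a filter, 50 with a minimum of 50, 15 with quantile normalization, 0 without the trend, 1 with a 1.2-fold minimum, 18 in edgeR and 52 in DESeq2. They were 0 among genes without overlap and 4 among genes with it, and from 1 to 164 with 1 library left out.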

Other observations

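Rows can also be read by the gene on their opposite strand, a reading chosen after the data were seen. There were 706 rows with at least 100 normalized counts whose exons overlap a single opposite-strand gene by at least 200 bp, and 21 of them were called in at least 1 comparison. In the TRPS1 knockdown, rises were in the rows opposite RBL2 (AKTIP, log2 fold change 1.14), KDM2B, a histone demethylase (RNF34, 1.10), KHNYN (SDR39U1, 1.12) and SERHL2 (RRP7BP, 1.41), and falls opposite AC006064.4 (GAPDH, -1.44) and AC011603.2 (TUBA1B, -1.20). In the HDAC2 knockdown, rises were opposite RBL2 (AKTIP, 0.99), AL390294.1 (GATA3-AS1, 1.21), MED12L (IGSF10, 1.10), CHPT1 (SYCP3, 1.13) and MYEF2 (SLC24A5, 1.00). Falls were opposite AC006064.4 (GAPDH, -1.31), AC126696.2 (SLC7A5, -1.36) and SYTL4, a vesicle trafficking gene (SRPX2, -1.19). Such rows may instead hold reads of the named gene, GAPDH or TUBA1B for example, so no change of the opposite gene is shown. Between the knockdowns 10 such rows were higher and 1 lower in the TRPS1 knockdown. The higher ones were opposite GLUD1, glutamate dehydrogenase (FAM35A, 1.21), ARL2BP (PLLP, 1.23), JMJD8 (STUB1, 1.08), BRI3BP (THRIL, 0.99), KCTD21 (KCTD21-AS1, 0.96), TMEM184A (MAFK, 1.23), PEX10 (RER1, 1.32), SERHL2 (RRP7BP, 1.72), RRP7A (SERHL, 1.10) and SH3BP5 (SH3BP5-AS1, 0.90), and the lower one opposite MED12L (IGSF10, -1.84). For FAM35A, PLLP, STUB1, RER1 and KCTD21-AS1, the larger change against the controls was a fall in the HDAC2 knockdown. For RRP7BP, SERHL, SH3BP5-AS1, MAFK and THRIL it was a rise in the TRPS1 knockdown. Of these 10 rows, only RRP7BP in the TRPS1 knockdown passed against the controls (limma, adjusted p = 0.00373).

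The row opposite the cyclin D1 gene CCND1 (ORAOV1) held 9543 and 9218 normalized counts in the TRPS1 knockdown against 4604 and 6414 in the controls of the same table, a log2 fold change of 0.79 with an SE of 0.25 that did not pass (limma, adjusted p = 0.191). The row opposite KRT18 (KRT8) had log2 fold changes of 0.00 (SE 0.34) in the TRPS1 knockdown and -0.34 (SE 0.35) in the HDAC2 knockdown, while the KRT18 row itself was at -0.85 and -0.82. The rows opposite 4 G2/M genes (CCNA2, CDCA3, CKAP2L and SGO1) had a median log2 fold change of 0.43 in the HDAC2 knockdown (camera, adjusted p = 0.0371 over 6 tests, and adjusted p = 0.53 with an estimated correlation) and -0.09 in the TRPS1 knockdown (0.669). Of the 4 rows, 0 passed singly in either knockdown.

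Of the tests that follow, the correlation within opposite-strand pairs, the fit without control replicate 1 and the correlation with separate controls were specified before their results were seen, and the others after, some of them in place of earlier tests. In a first pattern, abundant transcripts were listed low and genes overlapping them on the opposite strand were listed high. Assignment of reads without regard to strand is argued against, because 2.7% of the listed ribosomal protein genes without overlap were among the 500 highest rows, where an earlier test, medians of 37.8 for list members without overlap and 115 for overlapping rows, had left it open. Assignment of reads to the strand opposite to the annotated gene stays open as a candidate explanation. Under it, rows without overlap would hold mostly carried-over reads. The overlapping row was the higher in 72% of 25 pairs of list members (95% interval 50.6% to 87.9%), which did not decide it. The highest rows go with it, since 98 of 100 had opposite-strand overlap against 32.1% of all rows, but the pattern was drawn from them. The lower row of a pair may hold carried-over reads of the same transcript, since the fold changes of both rows correlated across pairs at 0.161 in the TRPS1 knockdown and 0.198 in the HDAC2 knockdown, where 1000 random pairings reached at most 0.106. No biological explanation of this pattern was tested, and the kit and strand setting are not given in the sources used here.

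In a second pattern, ribosomal protein and glycolysis genes were listed lower in both knockdowns. Control replicate 1 alone is argued against, because without it the ribosomal protein median stayed at -0.335 or lower in both comparisons. A lower share of carried-over reads in the knockdown libraries remains a candidate explanation, since the log2 ratio of the lower to the higher row of a pair changed by a median of -0.352 (95% interval -0.435 to -0.294) and -0.265 (-0.363 to -0.135), but the HDAC2 value missed the bound of -0.3 set for both, and a first version on 4 pairs of list members gave -0.408 (range -0.984 to -0.142) and -0.313 (-0.937 to 0.129). Whether the knockdowns lowered these transcripts cannot be told apart from that for members with an overlapping row: the 10 such rows had medians of -0.0401 and -0.00143, with lower interval ends down to -0.379 over 4 scalings in the TRPS1 knockdown and -0.234 in the HDAC2 knockdown, and over 9 members with a tested own row the median difference from it was 0.56 (96.1% interval 0.0773 to 1.30) and 0.321 (-0.14 to 1.49), so that neither test decided in both comparisons. Nor can it be told apart for the 49 members without overlap, whose own rows had medians of -0.595 (-0.68 to -0.489), below the change of the pairs, in the TRPS1 knockdown and -0.441 (-0.629 to -0.355), overlapping it, in the HDAC2 knockdown. All intervals of this pattern cover the spread over pairs, rows or genes, and not that between libraries.

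In the last pattern, the fold changes of the knockdowns went together across genes. Chance values of the shared controls cannot be told apart from a shared response. With separate controls the correlations were 0.17 and 0.249, and the bound set beforehand was above 0.2 in both. The 100 simulations with separate controls reached at most 0.0821, but they gave all groups the same dispersion. A library-wide difference in carry-over cannot be told apart either, because with separate controls rows with overlap correlated at 0.152 and 0.392, against 0.45 and 0.552 for rows without overlap at 100 or more normalized counts. The comparison set beforehand, with all rows without overlap (0.144 and 0.191), would have argued against it, but the same class correlated higher at 100 or more counts, so that comparison also measured read level. A response common to both knockdowns stays open as a hypothesis. If the controls, labelled "None", were not transfected, it could not be separated from transfection itself.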
